A study of Homo sapiens with 12 samples.

How the data were processed

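Gene expression was measured by RNA sequencing in THESC, an immortalized line of human endometrial stromal cells, the connective tissue cells of the lining of the uterus. Per the labels' protocols, the cells carried a CRISPR activation system, in which a guide RNA brings a transcriptional activator to a chosen gene without cutting the DNA. One kind of cell held a guide for ESR1, the gene of estrogen receptor alpha, and is called ESR1-activated here. The other held a control guide. Both were given 10 nM estradiol (E2, the main natural ligand of the receptor) or 0.01% ethanol as vehicle. Treatment lasted 24 h, in medium with 2% serum stripped with charcoal, a step that removes steroids. Total RNA was purified on columns with DNase, and libraries were made with a stranded kit for mRNA.

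The samples were grouped by guide and treatment as the labels give them, which made 4 groups of 3 libraries. The labels give 1 batch label for all 12 libraries, so no batch term could be fitted. That label does not exclude differences in handling between libraries. The labels do not say whether replicates of a group were separate cultures.

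The authors deposited a table of raw counts with whole numbers of reads for 61464 Ensembl genes in 12 libraries. Per the submitters' processing notes, the genome build was hg38 and the tools included STAR 2.6.0c, edgeR 4.2.2 and R 4.4.1. The notes give these tools no roles, and the counting program, its strand setting and the annotation release are not given in the sources used here. Counts of genes that overlap, on either strand, are therefore uncertain, as are those of near-identical paralogs. Of the genes named, IGF2, ADGRF4 and FGF5 overlap another protein-coding gene on the same strand. ABI3, CRELD2, CXCL14, DNAJB9, GPER1, IFIT2, IFIT3, KCNK15, KRT18, MTUS1, PTGER4 and SAMD11 overlap one on the other strand, and PGR, CCN5, KCNK15, MYLK, INHBA, CDKN2B, VCAN, ABCA8, IGF2 and SYNE1 a named antisense gene. Gene symbols came from the count table itself; 18942 genes had an identifier but no symbol and took 0.193% to 0.221% of the counts of a library. They stayed in the library totals and the tests. The authors also deposited a table of log2 CPM (counts scaled to library size, on a log2 scale) for 10631 genes, per the file headers. From its values, each library differed from the log2 CPM of the raw counts by 1 offset, so a scaling factor had been applied; the rule by which those genes were kept is not stated. This table served as an alternative only. It also held 2 unnamed columns with 3 values each, which were not used.

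Count totals ran from 26534924 to 112554879 per library, at which 1 read was worth 0.00888 to 0.0377 CPM and 3 reads, the most that a count of 0 allows at 95% confidence, 0.0267 to 0.113 CPM. These values use the total counts, before the TMM scaling named below. Such limits cover counting error only, since reads were not tagged with molecular identifiers in the deposited table. Replicates of each group differed by more than sampling noise: the chi-square statistic per degree of freedom over genes was between 1.64 and 108, and each library was counted as its own replicate.

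The counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust estimation and TMM scaling. Genes with too few counts were removed with filterByExpr by group, which left 16420. All 12 libraries entered 1 model with a mean for each group, so that the groups shared 1 estimate of the spread. The 5 contrasts were E2 against vehicle in ESR1-activated cells, E2 against vehicle in control cells, ESR1-activated against control cells under vehicle, the same under E2, and the difference of the E2 effect between the guides. P-values were adjusted over all genes of a contrast by the Benjamini-Hochberg method, with a threshold of 0.05. In this text "rose" and "fell" refer to genes past that threshold. CPM values are scaled by TMM, and given as the mean ± SD of 3 libraries. Log2 fold changes are given with an SE, taken as their size divided by the square root of the F statistic. For large changes that involve a group with few counts, this SE can be smaller than counting error alone. Intervals of log2 changes rest on the same SE.

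Gene groups were tested for 21 lists of genes: estrogen receptor targets, nuclear receptors and coregulators, neighbours of ESR1 on chromosome arm 6q, decidualization, cell cycle, extracellular matrix, cytokines and inflammation, interferon response, growth factors, Wnt signalling, TGF-beta and YAP targets, estrogen and steroid metabolism, cholesterol synthesis, unfolded protein and integrated stress response, p53 targets and senescence, hypoxia and glycolysis, endometrial stromal markers, epithelial markers, endothelial markers, immune markers, and smooth muscle and myofibroblast markers. For each list the number of members past the threshold was counted, over all genes and adjusted over the list alone. Lists were tested with camera from limma 3.58.1, a test that compares a list with all other genes, at a preset correlation of 0.01 and adjusted over the 21 lists of a contrast. Camera with a correlation estimated for each list, and fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, stood beside it.

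The groups, the tests, the gene lists, the rule for naming genes and the alternatives were set before the data were examined, except where stated. Genes are named by this rule. ESR1 is named in every group. In each contrast, the 10 largest rises and the 10 largest falls are named among genes past the threshold with a mean log2 CPM of at least 0 and no overlap between the CPM of the groups compared; overlap was not asked for the difference of the E2 effect. Chance alone gives no overlap in 10% of comparisons of 3 against 3. Clone-style names, antisense genes, small RNAs, pseudogenes, and genes of the X-inactivation centre or the Y chromosome were passed over. Up to 4 members of each list with the smallest p in a contrast are named, as are 13 genes that a reader of this field would look up: PGR, GREB1, TFF1, IGF1, CXCL12, PRL, IGFBP1, MKI67, IL6, ESR2, GPER1, CCDC170 and SYNE1. The text takes its examples from those genes, except where it says that a gene was chosen later.

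Gene positions are GRCh38 coordinates, counted from 1, of GENCODE release 29, matched by Ensembl identifier; whether the authors used that release is not known.

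The alternatives were edgeR with RLE factors, upper-quartile factors or library size alone; no filter, or a CPM of at least 1 in 3 libraries; DESeq2 1.42.0, limma-voom, and limma-trend on the deposited log2 CPM; a fit without robust estimation; only the libraries of the groups compared; the replicate number as a block; each library left out in turn; an adjusted p of 0.01; and at least a 2-fold change. Added after the data were seen were a fit with every library thinned to the smallest total, the gene lists without control vehicle replicate 3, and the nuclear receptor list without ESR1.

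Comparisons that share libraries share their chance values. For the overlap of the E2 response with the effect of the guide under vehicle, 20 sets of unchanged counts were simulated on the real means and library sizes. Each count of genes was also set against other divisions of the same libraries, all 10 for 3 against 3 and 60 drawn relabelings of treatment within each guide for the difference of the E2 effect.

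The tests were checked on simulated data with 200 changed genes per contrast among 16420. For E2 in ESR1-activated cells the test recovered 48% of genes changed 1.25-fold, 68% of those changed 1.5-fold, 86% of those changed 2-fold and 96% of those changed 4-fold. For E2 in control cells it recovered 48%, 64%, 78% and 100% of the same sizes. For the guide under vehicle it recovered 62%, 70%, 74% and 90%, for the guide under E2 44%, 56%, 80% and 92%, and for the difference of the E2 effect 32%, 62%, 64% and 86%. The share of calls that were false was 3.25%, 8.81%, 6.92%, 5.56% and 1.61% in that order of contrasts. For E2 in ESR1-activated cells, camera called 10 of 10 lists shifted by 0.5 on the log2 scale and 0 of 10 lists left unshifted. Apart from the changed genes, these simulations drew every library around the same mean levels. No simulated library therefore stood apart as control vehicle replicate 3 did in the data. Recovery in the real data may be lower, also for E2 in control cells.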

Results

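Transcript levels were compared in 12 libraries of THESC cells that differed in the guide they carried and in treatment, with 3 libraries per group. The control vehicle libraries held 35784023, 60921321 and 112554879 counts, and the control E2 libraries 38450866, 38027376 and 26788795. The ESR1-activated libraries held 26534924, 34521999 and 46232412 counts under vehicle and 38797167, 37536269 and 32387849 under E2. Since the labels do not state that replicates were separate cultures, the p-values measure the spread between these samples, which may be technical.

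ESR1 was high in every library with its guide and low in every control library, with 12 to 34 counts. ESR1 (ENSG00000091831, chromosome 6, 151656691 to 152129619, plus strand) stood at 0.444 ± 0.119 CPM (SD, n = 3) in control cells under vehicle and at 0.472 ± 0.215 CPM under E2. In ESR1-activated cells it stood at 263 ± 6.28 CPM under vehicle and 343 ± 5.997 CPM under E2. With the guide it was thus higher by 9.32 ± 0.093 (log2, SE) under vehicle and by 9.58 ± 0.10 under E2, and no library went against its label. With so few control counts, these SE are smaller than counting error alone would give. The end of ESR1 overlaps SYNE1 on the opposite strand, and the strand setting of the counting is not known. ESR2, the gene of the other estrogen receptor, was too low to test, with 18, 8, 8 and 13 counts in the 3 libraries of each group together.

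The first principal component of the tested genes held 35.4% of the variance and ordered the libraries by guide and, among ESR1-activated cells, by treatment. The second held 17.8% and set control vehicle replicate 3 at −42.7, away from the other 11 libraries, which lay between −8.91 and 14.7. That library was the deepest, and its counts had the highest shares of mitochondrial genes (2.58%), ribosomal protein genes (2.74%) and collagen genes (4.87%). Its deviations were taken from the mean of the other control vehicle libraries, for genes with a mean count of at least 100. The median deviation was 0.29 (log2) for extracellular matrix genes, 0.16 for endometrial stromal markers and 0.12 for smooth muscle markers. It was 0.11 for unfolded protein response genes and −0.17 for 4 endothelial markers.

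**Figure D1:**
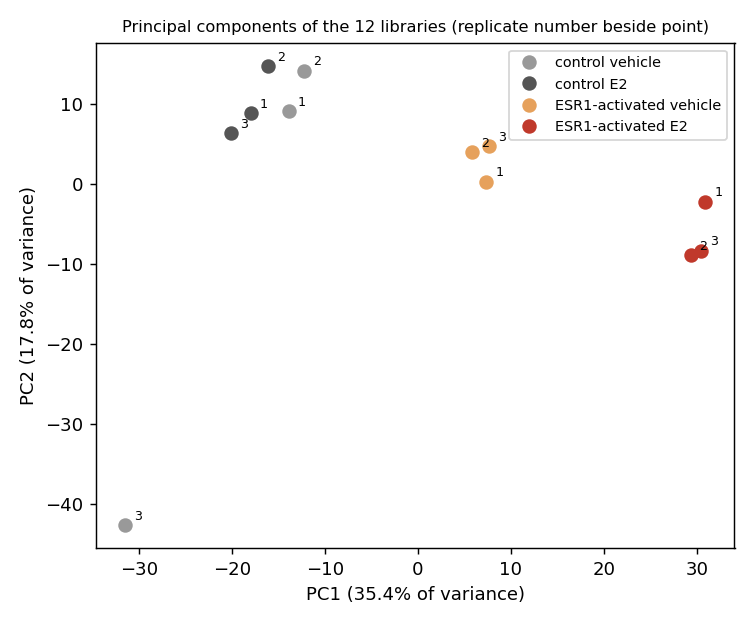
Principal components of the 12 libraries from log2 CPM of the tested genes, with PC1 (35.4% of variance) on the x axis and PC2 (17.8%) on the y axis. Each point is a library, coloured by group and marked with its replicate number; control vehicle replicate 3 lies apart at a PC2 of −42.7.

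The first comparison asked how cells with active ESR1 respond to E2. PGR, which codes for the progesterone receptor and is a classical target of estrogen receptor alpha (ENSG00000082175, chromosome 11, 101029624 to 101130524), rose from 44.0 ± 3.37 to 278 ± 4.85 CPM (SD, n = 3), a log2 change of 2.66 ± 0.050 (SE). Larger folds came from genes that were low under vehicle. SYTL5, of the synaptotagmin-like family of vesicle transport (ENSG00000147041, chromosome X, 38006582 to 38128819), rose 25.9-fold from 0.565 to 15.1 CPM. The potassium channel gene KCNK15 rose 18.1-fold, and CCN5, which codes for a secreted matricellular protein (ENSG00000064205, chromosome 20, 44714844 to 44728509), rose 16.9-fold from 0.592 to 10.1 CPM. Both genes overlap the antisense gene KCNK15-AS1.

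ANOS1, coding for the matrix protein anosmin, rose 15.6-fold, LONRF2 13.0-fold, the chemokine gene CXCL14 8.44-fold, the neurofilament gene NEFM 6.54-fold, the bone morphogenetic protein gene BMP6 5.03-fold and the galectin gene LGALS9 3.80-fold. Falls were smaller. FGF9, a fibroblast growth factor, fell from 18.4 ± 0.747 to 7.49 ± 0.424 CPM, which is 2.46-fold lower. Periostin (POSTN) was 2.37-fold lower, from 389 to 164 CPM, and the receptor gene KIT 2.08-fold lower, from 47.5 to 22.9 CPM. PADI2, a protein-arginine deiminase, was 3.49-fold lower, but on 49 and 14 counts in the 3 libraries of each group. The genes SYNPO2L, RASGRP3, DUSP2, SLC7A14, LYPD6B and MTUS1 also fell, with log2 changes of −1.06 to −0.94.

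By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1565 of 16420 genes passed, 788 upward and 777 downward. Most changes were small, with a median size of 0.30 (log2), and 127 rises but only 18 falls reached 2-fold. With library size as the sole scaling 1017 genes passed.

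**Figure D2:**
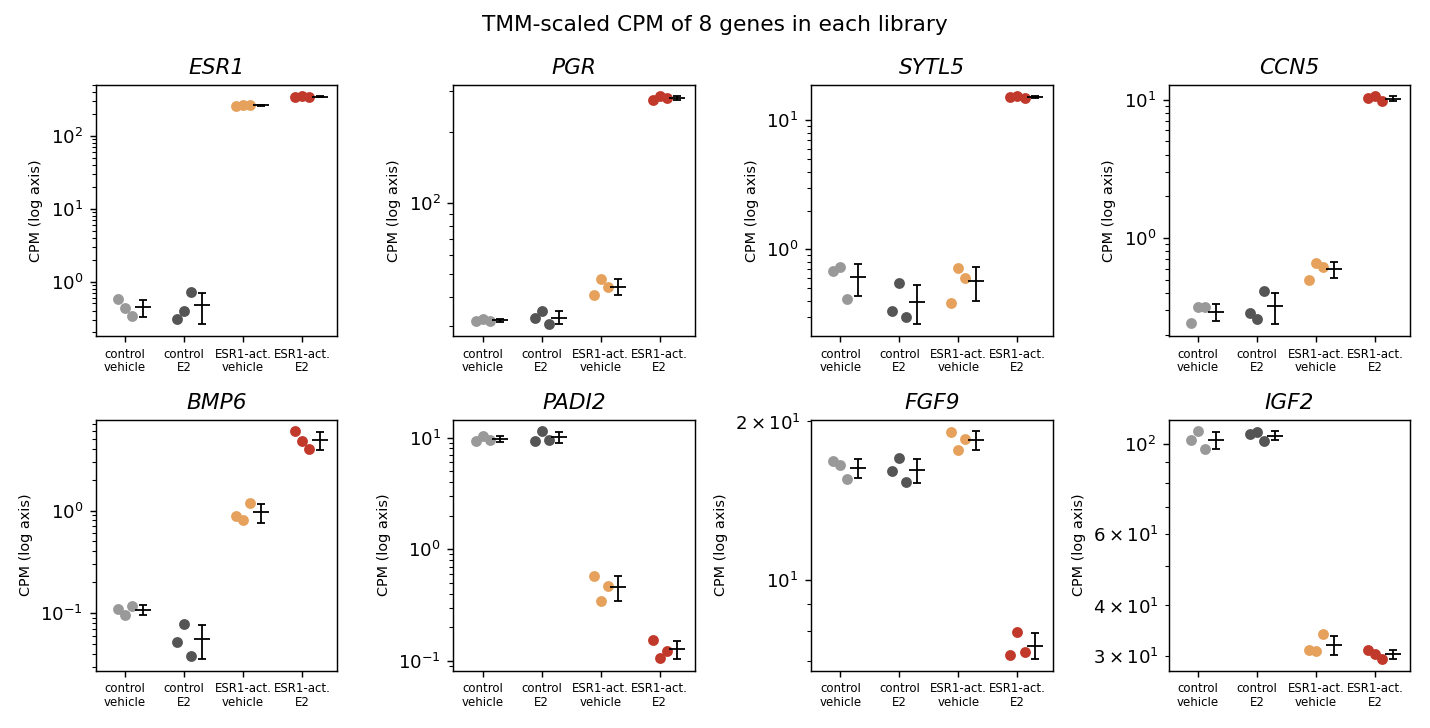
TMM-scaled CPM (log axis) of 8 genes in each of the 12 libraries, with the mean and SD of each group of 3 beside the points. ESR1 rises with the guide, PGR, SYTL5 and CCN5 are highest in ESR1-activated cells under E2, and IGF2 is lower with the guide under both treatments.

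Estrogen receptor targets led the response by list. Of 30 measured targets, 12 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 7.78e-18, and adjusted p = 0.00115 with an estimated correlation). Beside PGR and CCN5, NRIP1, a corepressor of nuclear receptors, rose by 0.51 ± 0.045 (log2, SE), TSKU by 0.56 ± 0.069 and the carbonic anhydrase gene CA12 by 0.29 ± 0.041. GREB1, often used as a reporter of estrogen action, stood at only 0.195 ± 0.0936 and 0.365 ± 0.177 CPM, and its log2 change of 0.83 ± 0.47 did not pass (adjusted p = 0.383). TFF1 had 0 counts in all 12 libraries, which allows up to 0.0267 CPM in the deepest and 0.113 CPM in the shallowest before TMM scaling. With the TMM factors of these libraries, 0.904 and 0.981, the limits are slightly higher. CXCL12 was abundant at 660.0 and 618 CPM and did not pass either (log2 −0.094 ± 0.060, adjusted p = 0.449).

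Among nuclear receptors and coregulators 6 of 26 rose and 1 fell (7 and 4 adjusted over the list alone). ESR1 itself rose by 0.38 ± 0.051, AR, the androgen receptor gene, by 0.39 ± 0.054 and GPER1, of a membrane estrogen receptor, by 0.61 ± 0.10. PGR (2.66) and NRIP1, which are also on the list of estrogen receptor targets, were among the 6. No test left them out, so the call is not separate from that of the targets. The ESR1 rise did not pass with limma-trend on the deposited log2 CPM. Camera called the list upward although its median was −0.016 (adjusted p = 2.12e-06, but adjusted p = 0.0861 with an estimated correlation and 0.137 without the filter). When control vehicle replicate 3 was left out, 7 rose and 3 fell. That library is not in this contrast but enters the spread that all groups share, which also holds for such counts in the lists below.

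Growth factor genes moved downward as a list. Among 28 growth factors, 4 rose and 12 fell (4 and 14 adjusted over the list alone; camera adjusted p = 4.71e-05, and adjusted p = 0.0117 with an estimated correlation). With FGF9, the EGF receptor ligand HBEGF (log2 −0.49 ± 0.048) and the activin subunit INHBA (−0.36 ± 0.047) fell, while BMP6 rose. Of 15 smooth muscle and myofibroblast markers, 0 rose and 6 fell (0 and 7 adjusted over the list alone). They included LMOD1 (−0.62 ± 0.042), the myosin light chain kinase MYLK (−0.45 ± 0.050) and calponin (CNN1, −0.44 ± 0.051). Camera gave that list an adjusted p of 2.85e-07, but adjusted p = 0.0861 with an estimated correlation (0.0403 without control vehicle replicate 3). The extracellular matrix list had 3 rises and 8 falls in 39 genes (4 and 10 adjusted over the list alone), with POSTN, the collagen COL8A1 (−0.69 ± 0.047) and the aggrecanase ADAMTS5 (−0.63 ± 0.045) down and stromelysin (MMP3, 1.03 ± 0.063) up. Its camera adjusted p was 0.00111, but adjusted p = 0.567 with an estimated correlation. Without control vehicle replicate 3, 6 rose and 13 fell, while the list median was −0.085 against −0.083 with all libraries.

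Part of the unfolded protein response genes rose. Of 23 on the list for the unfolded protein and integrated stress response, 7 rose and 0 fell (8 and 0 adjusted over the list alone), among them the endoplasmic reticulum proteins MANF (log2 0.43 ± 0.041), DNAJB9 (0.57 ± 0.087), CRELD2 (0.33 ± 0.041) and the chaperone HYOU1 (0.32 ± 0.042). The camera adjusted p was 4.71e-05, but adjusted p = 0.244 with an estimated correlation. Targets of p53 and senescence genes showed 0 rises and 5 falls in 22 (0 and 8 adjusted over the list alone; GDF15 −0.42 ± 0.10). Interferon response genes showed 0 rises and 3 falls in 22 (0 and 4 adjusted over the list alone; IFIT2 −0.57 ± 0.037). Camera called both downward, at adjusted p = 0.00801 and 0.0114. With an estimated correlation the values were adjusted p = 0.0861 and adjusted p = 0.124. In the p53 and senescence list 0 rose and 8 fell without control vehicle replicate 3.

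Genes of decidualization, the change that stromal cells undergo to receive an embryo, moved both ways. Of 20, 2 rose and 6 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.565). HSD11B1, the enzyme that regenerates active glucocorticoid, rose 6.83-fold from 0.322 to 2.23 CPM, the transcription factor FOXO1 rose 2.25-fold, and IGFBP3 fell (log2 −0.57 ± 0.076). The classical secreted markers were too low to test, with 0 and 2 counts of PRL and 5 and 16 of IGFBP1 in the vehicle and E2 groups. IGF1 and IL6 were also too low, at 0.0731 and 0.0990 CPM under E2.

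Few proliferation genes passed. In the cell cycle list 0 of 30 genes rose and 1 fell (0 and 0 adjusted over the list alone), and the proliferation marker MKI67 stood at 207 ± 6.72 and 214 ± 18.05 CPM (log2 0.045 ± 0.068, adjusted p = 0.832). Camera did not call the 10 remaining lists measured in the E2 response of ESR1-activated cells. Cytokine genes had 4 rises, with TNFAIP3 at 0.58, and 4 falls, with PTGER4 at −0.63, in 14 (6 and 6 adjusted over the list alone). Genes of Wnt signalling had 1 rise, SFRP1 at 1.16, and 2 falls, with FZD7 at −0.43, in 17 (1 and 3 adjusted over the list alone). TGF-beta and YAP targets had 3 rises, with LTBP1 at 0.76, and 6 falls, with CCN2 at −0.47, in 24 (3 and 7 adjusted over the list alone). For hypoxia and glycolysis 2 of 20 rose, with VEGFA at 0.32, and 4 fell, with HK2 at −0.43 (2 and 4 adjusted over the list alone). Steroid metabolism had 2 rises and 0 falls in 14 (3 and 0 adjusted over the list alone), and cholesterol synthesis 2 and 0 in 24 (2 and 0 adjusted over the list alone), with PCSK9 at 0.72. Leaving out control vehicle replicate 3 gave rises and falls of 1 and 1 for the cell cycle, 1 and 4 for Wnt signalling, 4 and 10 for TGF-beta and YAP targets, 4 and 5 for hypoxia and glycolysis, 4 and 0 for steroid metabolism and 2 and 2 for cholesterol synthesis.

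Stromal and epithelial markers moved both ways. Endometrial stromal markers had 3 rises and 4 falls in 19 (4 and 8 adjusted over the list alone; 3 and 8 over all genes without control vehicle replicate 3), and NT5E, the surface marker CD73, rose from 529 to 933 CPM. Epithelial markers had 1 rise, KRT19 at 0.49, and 2 falls, with KRT18 at −0.24, in 10 (1 and 2 adjusted over the list alone). Endothelial markers had 0 rises and 1 fall, TEK at −0.26, in 6 (0 and 1 adjusted over the list alone). Immune markers had 0 rises and 1 fall in 4 (0 and 1 adjusted over the list alone); it was PTPRC (CD45, −0.40), which did not pass with library size alone, DESeq2, limma-voom, thinned counts, or without replicate 2 or 3 of either ESR1-activated group.

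**Figure D3:**
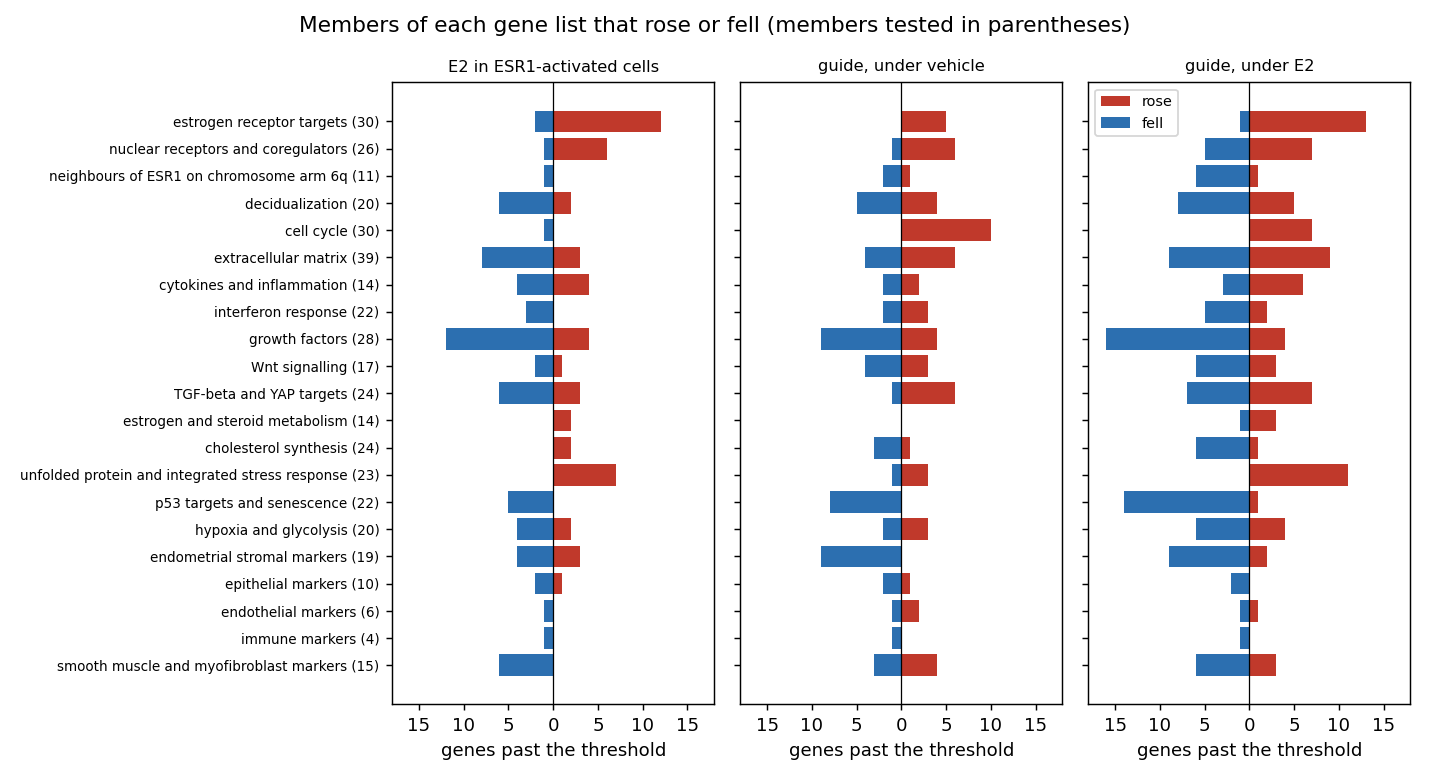
Number of members of each of the 21 gene lists that rose (right) or fell (left) past an adjusted p of 0.05 in 3 comparisons, with the number of members tested in parentheses. With E2 in ESR1-activated cells, 12 of 30 estrogen receptor targets rose and 12 of 28 growth factors fell.

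The control cells showed no E2 response that passed the test. PGR stood at 31.7 ± 0.437 CPM under vehicle and 32.6 ± 2.08 CPM under E2, a log2 change of 0.040 with a 95% interval of −0.061 to 0.14. SYTL5 stood at 0.606 and 0.395 CPM, and POSTN at 221 and 222 CPM. By edgeR 0 of 16420 genes passed, with 1074 at an unadjusted p under 0.05 where chance gives 821; DESeq2 and limma-voom also called 0. Without the filter on low counts 82 genes passed, 7 upward and 75 downward, and 1 gene passed when either control vehicle replicate 2 or ESR1-activated vehicle replicate 1 was left out. Without control vehicle replicate 3, 0 genes passed and 2084 were at an unadjusted p under 0.05. Adjusted over each list alone, VEGFA fell (−0.16) in the hypoxia and glycolysis list, and no member of the other 20 lists passed. Camera called the cell cycle list (adjusted p = 0.000314, but adjusted p = 0.861 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.00107, but adjusted p = 0.238 with an estimated correlation), each with a median change of 0.048. Without control vehicle replicate 3 the cholesterol call also held with an estimated correlation (adjusted p = 0.0201), and camera called 3 more lists upward. They were extracellular matrix (adjusted p = 1.43e-06, but adjusted p = 0.422 with an estimated correlation), stromal markers (adjusted p = 0.000186, but adjusted p = 0.367 with an estimated correlation) and TGF-beta and YAP targets (adjusted p = 0.000798, but adjusted p = 0.422 with an estimated correlation). With ESR1 left out of the nuclear receptors, camera called that list too (adjusted p = 0.0493, but adjusted p = 0.866 with an estimated correlation).

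The difference of the E2 effect between the guides was tested directly. PGR responded more in ESR1-activated than in control cells by 2.62 ± 0.071 (log2, SE), SYTL5 by 5.22 ± 0.33, CCN5 by 4.02 ± 0.26 and CXCL14 by 3.23 ± 0.23. The difference was negative for FGF9 (−1.29 ± 0.090), POSTN (−1.25 ± 0.080) and KIT (−1.02 ± 0.074). It passed for 797 genes, 377 positive and 420 negative (489 with library size as the sole scaling). Of these, 769 were also among the 1565 genes called for E2 in ESR1-activated cells, all in the same direction, though both tests use the same ESR1-activated libraries. The slope of the control on the ESR1-activated log2 change over the 1565 genes was −0.016. Of these genes, which are not independent replicates, 55.8% changed with the same sign in control cells.

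By list, the difference was positive for estrogen receptor targets, with 8 positive and 1 negative of 30 (14 and 1 adjusted over the list alone; camera adjusted p = 1.43e-14, and adjusted p = 0.00385 with an estimated correlation). It was negative for growth factors, with 2 positive and 10 negative of 28 (4 and 13 adjusted over the list alone; camera adjusted p = 4.75e-06, and adjusted p = 0.00511 with an estimated correlation). The unfolded protein list had 4 positive and 0 negative members (6 and 0 adjusted over the list alone; camera adjusted p = 6.13e-06, but adjusted p = 0.242 with an estimated correlation). Smooth muscle and myofibroblast markers had 0 and 5 (0 and 6 adjusted over the list alone; camera adjusted p = 4.75e-06, but adjusted p = 0.116 with an estimated correlation), and 0 and 9 without control vehicle replicate 3. Extracellular matrix genes had 2 and 6 (2 and 7 adjusted over the list alone; camera adjusted p = 0.00562, but adjusted p = 0.630 with an estimated correlation); without control vehicle replicate 3 these were 2 and 14. Nuclear receptors had 3 and 1 (6 and 2 adjusted over the list alone), with a median of −0.047 but an upward call (camera adjusted p = 0.00414, but adjusted p = 0.242 with an estimated correlation and 0.942 without the filter). PGR (2.62) and NRIP1 (0.43), which are also on the list of estrogen receptor targets, were among the 3. The p53 and senescence list had 0 and 0 (0 and 3 adjusted over the list alone; camera adjusted p = 0.00434, but adjusted p = 0.0995 with an estimated correlation). Camera did not call the other 14 lists for this difference, but without control vehicle replicate 3 it called TGF-beta and YAP targets (1 and 8; adjusted p = 0.0162, but adjusted p = 0.266 with an estimated correlation) and endometrial stromal markers (1 and 7; adjusted p = 0.00527, but adjusted p = 0.242 with an estimated correlation). The smooth muscle call then also held with an estimated correlation (adjusted p = 0.0244). Leaving out that library also gave 10 and 2 for estrogen receptor targets, 6 and 3 for nuclear receptors and 0 and 1 for the p53 and senescence list.

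**Figure D4:**
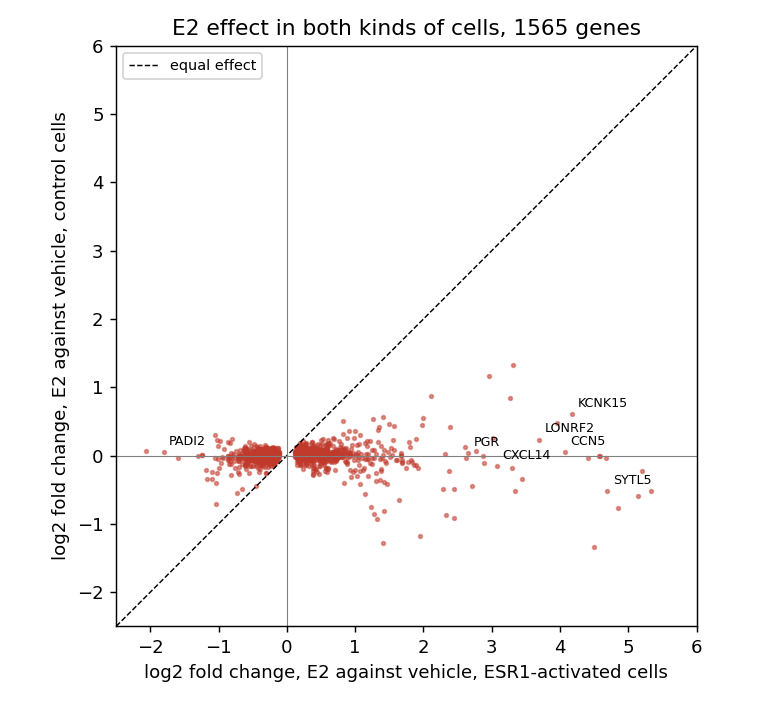
Log2 fold change of E2 against vehicle in control cells (y axis) against that in ESR1-activated cells (x axis) for the 1565 genes called in ESR1-activated cells, each point a gene. The points lie along the x axis and away from the dashed line of equal effect, and the slope over these genes is −0.016.

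The guide went with changes in expression without added E2. Beside ESR1 itself, BMP6 rose 8.75-fold, on 22 and 107 counts in the 3 libraries of each group. ID4, an inhibitor of DNA binding, rose from 5.55 ± 0.304 to 13.7 ± 0.0643 CPM, and SAMD11, TPD52, FIBCD1, LONRF2 and ADAMTS12 rose 2.37-fold to 2.49-fold. PGR rose from 31.7 ± 0.437 to 44.0 ± 3.37 CPM (log2 0.47 ± 0.051). Large falls were in PADI2, 21.3-fold lower from 9.73 to 0.463 CPM (ENSG00000117115, chromosome 1, 17066761 to 17119435), and in the hair cell synapse gene OTOF, 14.01-fold lower from 6.02 to 0.430 CPM. The fetal growth factor IGF2 fell from 102 ± 5.00 to 32.0 ± 1.73 CPM (ENSG00000167244, chromosome 11, 2129112 to 2149603), a gene that overlaps INS-IGF2. ADGRF4, SYTL1, the cell adhesion gene ESAM, the integrin ITGAX, ABCA8, ABI3 and the transcription factor FOXE1 were 2.82-fold to 3.88-fold lower.

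In all, 1555 genes passed between ESR1-activated and control cells under vehicle, 723 higher and 832 lower, of which 56 and 51 reached 2-fold. The count was 822 with library size alone, 861 with only the libraries of both groups, 910 without ESR1-activated vehicle replicate 3, 1021 without ESR1-activated vehicle replicate 1 and 1573 without control vehicle replicate 3. The rises of KCNK15 (1.38) and NEFM (1.32) did not pass on thinned counts, nor did KCNK15 when only both groups were fitted. The labels name no separate cell pools with the same guide, so that an effect of the guide and of the pool that carried it are the same comparison.

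With the guide under vehicle, part of the cell cycle genes rose and part of the stromal markers fell. In the cell cycle list 10 of 30 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.71e-05, but adjusted p = 0.315 with an estimated correlation), including E2F1 (log2 0.40 ± 0.077), MYBL2 (0.32 ± 0.060) and CDC6 (0.27 ± 0.053). Of 19 endometrial stromal markers, 0 rose and 9 fell (1 and 11 adjusted over the list alone; camera adjusted p = 3.23e-07, but adjusted p = 0.247 with an estimated correlation). They included the matrix proteoglycans decorin (DCN, −0.63 ± 0.075) and lumican (LUM, −0.47 ± 0.066) and the receptor gene PDGFRA (−0.32 ± 0.039). Control vehicle replicate 3 was high in these markers (median deviation 0.16), and without it 4 rose and 9 fell.

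Growth factors had 4 rises and 9 falls in 28 (5 and 11 adjusted over the list alone; camera adjusted p = 0.000523, and adjusted p = 0.0245 with an estimated correlation), with IGF2, FGF5 (−0.58 ± 0.050) and the angiopoietin gene ANGPT1 (−0.54 ± 0.038) down. In the p53 and senescence list 0 rose and 8 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0130, but adjusted p = 0.118 with an estimated correlation), with the cell cycle inhibitor CDKN2B at −0.48 ± 0.052. Estrogen receptor targets had 5 rises and 0 falls (7 and 1 adjusted over the list alone; camera adjusted p = 0.0310, but adjusted p = 0.165 with an estimated correlation), among them PGR, EGR3 (0.93 ± 0.15) and NRIP1 (0.24 ± 0.045). Nuclear receptors, a list that holds ESR1 itself, had 6 and 1 (6 and 1 adjusted over the list alone; camera adjusted p = 6.22e-22, and adjusted p = 0.00619 with an estimated correlation). Without ESR1, whose rise the guide sets, it was not called (adjusted p = 0.0856, and adjusted p = 0.494 with an estimated correlation). Among TGF-beta and YAP targets 6 rose, with ID1 at 0.47, and 1 fell (7 and 2 adjusted over the list alone). Camera gave them adjusted p = 0.0492, but adjusted p = 0.352 with an estimated correlation and 0.0581 with the replicate block. Cholesterol synthesis had 1 rise and 3 falls (1 and 3 adjusted over the list alone). Camera gave it adjusted p = 0.0422, but adjusted p = 0.247 with an estimated correlation, and 0.0721 without control vehicle replicate 3. Of its members, the fall of MSMO1 did not pass with RLE or upper-quartile factors, limma-voom, a fit without robust estimation, only both groups fitted or thinned counts. It also did not pass without control vehicle replicate 3, without any ESR1-activated vehicle replicate, or without some other libraries. The rise of PCSK9 did not pass with library size alone or without ESR1-activated vehicle replicate 3. Of 4 immune markers, PTPRC fell from 8.16 to 3.35 CPM (camera adjusted p = 0.0310, but adjusted p = 0.165 with an estimated correlation and 0.403 without the filter). When control vehicle replicate 3 was left out, rises and falls were 5 and 1 for estrogen receptor targets, 5 and 2 for nuclear receptors and 7 and 2 for TGF-beta and YAP targets.

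Camera did not call the other lists for the guide under vehicle. Extracellular matrix genes had 6 rises and 4 falls (6 and 5 adjusted over the list alone), with POSTN at 0.82 and MMP3 at 0.92 up. Control vehicle replicate 3 was high in this list (median deviation 0.29), and without it 16 rose and 4 fell (camera adjusted p = 0.226 with all libraries and 3.16e-07 without it, but adjusted p = 0.172 with an estimated correlation). Decidualization genes had 4 and 5 (4 and 6 adjusted over the list alone; IGFBP5 at 0.95), cytokines 2 and 2 (3 and 2 adjusted over the list alone; PTGES at 0.62, PTGER4 at −0.61) and the interferon response 3 and 2 (3 and 3 adjusted over the list alone; IFIT3 at 0.29, IFI44 at −0.59). Smooth muscle markers had 4 and 3 (4 and 3 adjusted over the list alone; MYLK at −0.50, LMOD1 at −0.54), and hypoxia and glycolysis 3 and 2 (3 and 2 adjusted over the list alone; VEGFA at 0.25, ALDOC at −0.45). Endothelial markers had 2 and 1 in 6 (2 and 2 adjusted over the list alone), with TIE1 at 0.78 and ESAM at −1.85, and the unfolded protein list 3 and 1 in 23 (5 and 1 adjusted over the list alone). Without control vehicle replicate 3, camera called the endothelial (2 and 2; adjusted p = 0.000822, and adjusted p = 0.0460 with an estimated correlation) and the unfolded protein list (5 and 1; adjusted p = 0.000938, but adjusted p = 0.197 with an estimated correlation). Wnt signalling had 3 and 4 (5 and 5 adjusted over the list alone), epithelial markers 1 and 2 (1 and 4 adjusted over the list alone) and steroid metabolism 0 and 0 (0 and 0 adjusted over the list alone). Leaving out the same library gave 5 and 3 for decidualization, 3 and 4 for the interferon response and 0 and 4 for epithelial markers.

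Under E2 the guide separated the cells more widely. PGR stood 8.53-fold higher in ESR1-activated than in control cells, SYTL5 37.1-fold, CCN5 32.4-fold, KCNK15 30.9-fold, LONRF2 27.1-fold, NEFM 22.1-fold, CXCL14 15.6-fold and ANOS1 14.9-fold. BMP6 rose 80.9-fold against a control group with 6 counts in 3 libraries, so that this fold is poorly fixed. Its log2 interval, 5.78 to 6.90, rests on the SE and is too narrow for so few counts. PADI2 fell 77.1-fold, from 10.1 to 0.128 CPM, a fold also poorly fixed, on 6, 4 and 4 counts in the ESR1-activated libraries. OTOF fell 3.70-fold, from 5.62 to 1.52 CPM. LYPD6B, ESAM, C11orf87, FOXE1, IGF2, PTPRC, SYTL1 and ITIH3 were 3.28-fold to 4.10-fold lower. By edgeR 3523 genes passed, 1644 higher and 1879 lower, of which 269 and 130 reached 2-fold.

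By list, estrogen receptor targets had 13 rises and 1 fall in 30 (19 and 1 adjusted over the list alone; camera adjusted p = 5.03e-13, and adjusted p = 0.00211 with an estimated correlation), with NRIP1 at 0.67. Growth factors had 4 and 16 in 28 (4 and 16 adjusted over the list alone; camera adjusted p = 9.33e-09, and adjusted p = 0.00211 with an estimated correlation), with ANGPT1 at −0.91. The p53 and senescence list had 1 rise and 14 falls in 22 (1 and 16 adjusted over the list alone; camera adjusted p = 8.47e-05, and adjusted p = 0.0220 with an estimated correlation, which was 0.0622 without control vehicle replicate 3), with GDF15 at −0.77, BTG2 at −0.63 and ZMAT3 at −0.38. Nuclear receptors had 7 and 5 (8 and 7 adjusted over the list alone; camera adjusted p = 1.57e-16, and adjusted p = 0.00758 with an estimated correlation, but 0.126 without the filter), GPER1 among them at 0.66. Without ESR1 the list had a median of 0.0096 (camera adjusted p = 0.00109, but adjusted p = 0.218 with an estimated correlation and 0.480 without the filter). It still held PGR and NRIP1, which are also on the list of estrogen receptor targets. Estrogen receptor targets had 18 and 2 without control vehicle replicate 3.

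The unfolded protein list had 11 rises and 0 falls in 23 (11 and 0 adjusted over the list alone; camera adjusted p = 8.80e-06, but adjusted p = 0.194 with an estimated correlation), with MANF at 0.63, HYOU1 at 0.56 and CRELD2 at 0.42. Stromal markers had 2 and 9 in 19 (3 and 11 adjusted over the list alone; camera adjusted p = 6.10e-05, but adjusted p = 0.347 with an estimated correlation), with DCN at −0.84 and LUM at −0.68. Smooth muscle markers had 3 and 6 in 15 (3 and 6 adjusted over the list alone; camera adjusted p = 0.000307, but adjusted p = 0.194 with an estimated correlation), with LMOD1 at −1.11 and MYLK at −1.01. Camera did not call the other lists for the guide under E2, in which decidualization genes had 5 rises, with HSD11B1 at 3.09, and 8 falls, with KLF9 at −0.67 (6 and 8 adjusted over the list alone). The cell cycle list had 7 rises and 0 falls (7 and 0 adjusted over the list alone; camera adjusted p = 0.0780). Extracellular matrix genes had 9 rises, with MMP3 at 1.79, and 9 falls (9 and 11 adjusted over the list alone), and cytokines 6, with PTGES at 0.85, and 3, with PTGER4 at −1.21 (6 and 4 adjusted over the list alone). Wnt signalling had 3, with SFRP1 at 1.68, and 6, with FZD7 at −0.74 (3 and 7 adjusted over the list alone), and hypoxia and glycolysis 4, with VEGFA at 0.72, and 6 (4 and 6 adjusted over the list alone). TGF-beta and YAP targets had 7 and 7 (9 and 8 adjusted over the list alone), cholesterol synthesis 1 and 6 (1 and 9 adjusted over the list alone), and the interferon response 2 and 5 (2 and 5 adjusted over the list alone). Steroid metabolism had 3 and 1, epithelial markers 0 and 2, endothelial markers 1 and 1 and immune markers 0 and 1 (3 and 1, 1 and 2, 1 and 1, and 0 and 1 adjusted over the list alone). Without control vehicle replicate 3, camera also called downward cholesterol synthesis (1 and 13; adjusted p = 0.0329, but adjusted p = 0.0845 with an estimated correlation), endothelial markers (adjusted p = 0.0370, but adjusted p = 0.0997 with an estimated correlation) and immune markers (adjusted p = 0.0470, but adjusted p = 0.112 with an estimated correlation). Leaving it out gave rises and falls of 12 and 15 for extracellular matrix, 6 and 5 for cytokines, 7 and 6 for hypoxia and glycolysis, 14 and 1 for the unfolded protein list, 4 and 11 for stromal and 1 and 2 for epithelial markers.

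The effects of the guide under vehicle and under E2, which share no library, were compared gene by gene. Among 1164 genes called under both treatments, 1121 moved in the same direction and 43 in opposite directions, where independent lists of these sizes would share 168 and 166. That reference treats every gene as equally likely to be called. DCN, IGF2, ESAM and PADI2 fell and ESR1, BMP6 and PGR rose under both. POSTN was higher with the guide under vehicle (log2 0.82), where its level was 389 against 221 CPM, and lower under E2 at 164 against 222 CPM. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.485 and a covariance of 0.0801, against −0.00108 and −4.87e-05 in simulations with no effect. The same-direction count was 723 without ESR1-activated vehicle replicate 3.

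The E2 response in ESR1-activated cells was compared in the same way with the effect of the guide under vehicle, which shares the ESR1-activated vehicle libraries with it. Of 517 genes called in both, 362 moved in the same direction and 155 in opposite directions, where independent lists would share 74.1 each way. That reference treats every gene as equally likely to be called, and the observed counts lie above it in both directions. PGR, LONRF2, BMP6, MMP3, NRIP1, MANF and HYOU1 rose and PADI2, LMOD1, MYLK, PTGER4 and GDF15 fell in both, while POSTN rose with the guide and fell with E2. In simulations without effects, the shared libraries alone gave a mean correlation across genes of −0.536 and a covariance of −0.0246, and at most 1 gene called in both; the observed correlation was 0.0204 and the covariance 0.00234. These simulations held less spread than the data, with variances of the log2 changes of 0.0490 and 0.0431 against 0.0846 for E2 in control cells, where no gene passed. The 3 shared libraries could not be divided so that each part kept 2, so part of the excess of opposite changes may come from them; by the negative covariance, they work against changes in the same direction. The same-direction count was 230, and the opposite count 89, without ESR1-activated vehicle replicate 3.

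Genes next to ESR1 on chromosome arm 6q were examined because the activator acts at that locus. Of 11 measured neighbours, 1 rose and 2 fell with the guide under vehicle (1 and 2 adjusted over the list alone; camera adjusted p = 0.495; 1 and 0 over all genes without control vehicle replicate 3), and 1 rose and 6 fell under E2 (1 and 8 adjusted over the list alone; camera adjusted p = 0.138). CCDC170, which ends upstream of ESR1 (ENSG00000120262, chromosome 6, 151494030 to 151621193), stood at 0.807 ± 0.149 CPM in control and 0.382 ± 0.118 CPM in ESR1-activated cells under E2 (log2 −1.07 ± 0.33). SYNE1, downstream (ENSG00000131018, chromosome 6, 152121684 to 152637801), was lower (log2 −0.26), and its count can include reads of ESR1. RGS17, farther downstream, was higher (1.05 ± 0.19). AKAP12 was higher with the guide under vehicle (0.25), lower under E2 (−0.22), and fell with E2 in ESR1-activated cells (−0.52). The CCDC170 call was lost with DESeq2 and without control E2 replicate 2 or 3 or ESR1-activated E2 replicate 1 or 2, and the SYNE1 call without any 1 of the 6 libraries compared. The AKAP12 call was lost under vehicle with only both groups fitted and without control vehicle replicate 1 or ESR1-activated vehicle replicate 3, and under E2 without ESR1-activated E2 replicate 1. With E2 in ESR1-activated cells 0 neighbours rose and 1, AKAP12, fell (1 and 3 adjusted over the list alone; 1 and 2 over all genes without control vehicle replicate 3).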

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

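The tests of control vehicle replicate 3 as a cause, of ESR1 acting without added E2, and of a difference between cell pools were chosen only after the results were seen. Those of depth, GC content and transcript length concern a library that was picked out by its values in these data.

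The effect of E2 differed between ESR1-activated and control cells, by the test of the difference itself, for 797 genes. Where the difference (log2, ESR1-activated minus control) was positive, the named genes of the largest size were SYTL5 5.22, CCN5 4.02, KCNK15 3.57, ANOS1 3.48, LONRF2 3.47, CXCL14 3.23, BMP6 3.21, NEFM 3.15, HSD11B1 2.70, PGR 2.62, LGALS9 2.10, OTOF 1.92, VCAN 1.31 and SFRP1 1.13. Smaller positive differences were FOXO1 0.96, MMP3 0.87, NT5E 0.82, LTBP1 0.74, KRT19 0.64, TNFAIP3 0.63, PCSK9 0.62 and ID4 0.54. The smallest were DNAJB9 0.50, TSKU 0.49, VEGFA 0.47, NRIP1 0.43, MANF 0.42, AR 0.41, CRELD2 0.36, HYOU1 0.32 and CA12 0.30. Where it was negative, the values were PADI2 −1.86, SYNPO2L −1.35, FGF9 −1.29, POSTN −1.25, DUSP2 −1.19, FHIP1A −1.06, KIT −1.02, GBP5 −1.02 and CD200 −1.01. The PADI2 value rests on few counts in ESR1-activated cells. Smaller negative ones were RASGRP3 −0.95, LYPD6B −0.93, MTUS1 −0.90, SLC7A14 −0.85, ADAMTS5 −0.70, COL8A1 −0.69, PTGER4 −0.60, LMOD1 −0.56, IFIT2 −0.53, CCN2 −0.52, MYLK −0.51, HBEGF −0.51 and IGFBP3 −0.50, and the smallest FZD7 −0.47, AKAP12 −0.47, CNN1 −0.44, INHBA −0.43, HK2 −0.40 and TEK −0.26. The difference for CD200 did not pass without control E2 replicate 1 (log2 −0.89, adjusted p = 0.0530) or on thinned counts. That for RASGRP3 did not pass under 7 alternatives, at log2 values of −0.98 to −0.80 and adjusted p of 0.0505 to 0.0986: library size alone, DESeq2, thinned counts, and without control vehicle replicate 2, control E2 replicate 1, ESR1-activated vehicle replicate 3 or ESR1-activated E2 replicate 1. When treatment was relabeled within each guide, 8 of 60 draws, the real one included, gave at least 797 genes, the highest other 1120. These were all the draws in which the ESR1-activated libraries kept their real treatment, and with it their E2 response, so their number was set by the drawing and the count cannot decide on chance. The 52 draws in which they did not gave 0 genes. In those draws E2 and vehicle libraries of ESR1-activated cells were mixed, so their E2 response widened the spread, and 0 is no measure of chance.

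Control vehicle replicate 3 lay apart from the other control vehicle libraries, with an SD over genes of its log2 deviation of 0.31 against at most 0.13 in the 9 libraries of the other groups. After all libraries were thinned to the smallest total, the SD was 0.25 against at most 0.12, over 10966 genes in place of 11708. Thinning evens out counting error but keeps the expected share of each gene. The thinned value therefore argues only against uneven counting error as the whole cause, and decides nothing on other causes that go with depth. After a trend on GC content was removed the SD was 0.30 against at most 0.12, and after a trend on transcript length 0.29 against at most 0.13. Both values argue against these trends as the whole cause. What made this library differ stays open, and no biological explanation was tested.

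Many genes differed between ESR1-activated and control cells without added E2. That control vehicle replicate 3 made this pattern is argued against, since 80.6% of the 1555 genes were called again without it. ESR1 acting without added E2 stays open: of the 517 genes also called for E2 in ESR1-activated cells, 70.0% moved in the same direction, where independent lists would share 74.1 genes each way. In simulations with the shared libraries and no effects at most 1.90% of the genes common to top-ranked lists of the same lengths did, but neither value holds both real effects and shared libraries, so the share decides nothing. For all 1555 genes, among them 1038 not called for E2, a difference between the cell pools other than ESR1 cannot be told apart from the guide, because each guide came with its own cells.

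No gene passed for E2 in control cells by edgeR, DESeq2 or limma-voom, with 1074 at an unadjusted p under 0.05 where chance gives 821; 82 passed without the filter, and 1 without control vehicle replicate 2 or without ESR1-activated vehicle replicate 1. Without control vehicle replicate 3, and so with fewer libraries, the edgeR count was also 0. This argues against that library as the sole cause of the count. Smaller shifts that it hid stay open, since 2084 genes were then at an unadjusted p under 0.05 and camera called extracellular matrix, stromal markers and TGF-beta and YAP targets upward (adjusted p = 1.43e-06, 0.000186 and 0.000798, but adjusted p = 0.422, 0.367 and 0.422 with an estimated correlation). For the 145 genes changed at least 2-fold in ESR1-activated cells, too little precision to see a response of that size is argued against. The control interval held the ESR1-activated value for 2.07% of them. Their median control change was −0.038 for the 127 rises and −0.037 for the 18 falls. Genes with smaller changes were not part of this test, and the median size over all 1565 called genes was 0.30. A response smaller than the median half-width of these intervals, 0.59, stays open.

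For the comparisons of 3 against 3 libraries, the 10 divisions are too few for a share under 0.05. For E2 in ESR1-activated cells, 1 of the 10 gave as many genes, the real one with 1565, and the highest other gave 0. For the guide, 1 of 10 did so under vehicle, the real one with 1555, and 1 of 10 under E2, the real one with 3523, and the highest other gave 0 in both. For E2 in control cells all 10 gave 0. Every division but the real one mixed libraries of both groups, so that real differences widened the spread. A count of 0 there is no measure of chance.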

How the results depend on the processing

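Among the tests of this part, those on counts thinned to the smallest library were chosen only after the results were seen.

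With library size as the sole scaling, 1017 genes passed for E2 in ESR1-activated cells, 822 for the guide under vehicle and 489 for the difference of the E2 effect. At an adjusted p of 0.01 the counts were 1032, 843, 2273 (guide under E2) and 510, and for the genes shared in the same direction 210 (E2 response and guide under vehicle) and 652 (guide under vehicle and under E2); a stricter threshold gives fewer genes by construction. With at least a 2-fold change they were 145, 107, 399 and 102. Without the filter 82 genes passed for E2 in control cells, and with only both groups fitted 861 passed for the guide under vehicle; the cause was not tested for these or for library size. With single libraries left out, the count was 1129 to 2094 for E2 in ESR1-activated cells, 0 to 1 for E2 in control cells, 910 to 1983 for the guide under vehicle, 2647 to 4371 for the guide under E2, 617 to 1063 for the difference, 230 to 423 for the first overlap and 723 to 1203 for the other. Every count stayed within 1.5 times of its value with RLE or upper-quartile factors, the stricter filter, DESeq2, limma-voom, limma-trend on the deposited log2 CPM, a fit without robust estimation and thinned counts, where these were run for it.

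Over 191 results of named genes, 4458 of 4522 alternative values kept direction and side of the threshold, 62 kept the direction but not the call, and 2 changed sign. These were PGR for E2 in control cells, at −0.0071 without control E2 replicate 2 (range without single libraries −0.0071 to 0.082), and MKI67 for E2 in ESR1-activated cells, at −0.011 without ESR1-activated E2 replicate 1 (range −0.011 to 0.11). Neither was called under any of them, and the cause was not tested. Of 132 values for the 33 camera calls, 100 remained calls in the same direction. Of the 32 lost, 23 were lost with an estimated correlation, 4 with fry, 4 without the filter and 1 with the replicate block. The estimated correlation gave the highest adjusted p of the 4 alternatives (estimated correlation, fry, no filter and replicate block) for every call except those of nuclear receptors in the E2 response, the guide under E2 and the difference, and of immune markers for the guide under vehicle, for which no filter did.

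Equal replicate numbers did not pair the libraries: over 18 pairs of equal number the correlation of deviations was −0.096 to 0.17, with 2 above 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate block 1547, 0, 1527, 3494 and 762 genes passed in the 5 contrasts, and 353 and 1087 were shared in the same direction. The block ended 1 call, that of TGF-beta and YAP targets for the guide under vehicle (adjusted p = 0.0581), and changed no other of the 33. With the block camera also called nuclear receptors and TGF-beta and YAP targets for E2 in control cells (adjusted p = 0.0492 for both) and endothelial markers for the guide under vehicle (0.0256) and under E2 (0.0483). Without the filter it also called the former lists (0.0296 for both), steroid metabolism in the E2 response of ESR1-activated cells (0.0264), the unfolded protein list for the guide under vehicle (0.0227), and neighbours of ESR1 (0.0180), cell cycle (0.00367) and cholesterol synthesis (2.47e-06) for the guide under E2. Depth limits genes near 1 read, worth 0.00888 to 0.0377 CPM before TMM scaling.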

Other observations

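The tests of OTOF and ID4 in the E2 response, of ID4 under E2 and of VCAN were chosen only after the results were seen.

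OTOF moved one way with the guide and the other way with E2. This gene, whose product serves vesicle release in hair cells, was lower with the guide under vehicle (log2 −3.81 ± 0.14, SE) and rose with E2 in ESR1-activated cells (1.83 ± 0.16), but at 1.52 CPM it stayed below the 5.62 CPM of control cells under E2. ID4 moved the same way in both, from 5.55 CPM in control cells to 13.7 CPM with the guide (1.30 ± 0.071) and 25.7 CPM with the guide and E2 (0.91 ± 0.066 for E2 and 1.84 ± 0.071 for the guide under E2). VCAN, coding for the matrix proteoglycan versican, rose with E2 in ESR1-activated cells from 49.2 to 119 CPM (1.27 ± 0.085) and was higher with the guide under E2 (1.44 ± 0.086), while its log2 change with the guide under vehicle was 0.13 ± 0.086 (adjusted p = 0.401 by edgeR).

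PTGES and PTGER4 moved in opposite directions with the guide. PTGES, the gene of a prostaglandin E synthase, stood at 12.03 ± 0.624 CPM in control cells and 18.5 ± 0.502 CPM in ESR1-activated cells under vehicle (SD, n = 3), and at 12.3 ± 0.803 and 22.3 ± 0.764 CPM under E2. PTGER4, the gene of a receptor for prostaglandin E2, stood at 34.1 ± 1.44 and 22.3 ± 0.950 CPM under vehicle and at 33.5 ± 0.755 and 14.5 ± 1.07 CPM under E2. All 4 differences between the guides passed edgeR's test.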
